A study of Caenorhabditis elegans with 12 samples.

How the data were processed

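Polyadenylated RNA of arrested first-stage (L1) Caenorhabditis elegans larvae was sequenced in 12 libraries, 4 for each of 3 RNAi treatments of the parents: bacteria with an empty vector, bacteria against daf-2 and bacteria against pitr-1. Per the labels, all animals carried hrde-1(tm1200), the parents grew on RNAi bacteria for 72 h, and the larvae were frozen about 24 h after the bleach that released the embryos. The labels call the 4 libraries of a group biological replicates, and do not say whether libraries of the same replicate number were made on the same day. The kit named in the labels does not mark strand, so reads of a gene and of an antisense partner cannot be told apart.

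The authors deposited whole-number read counts per gene, 1 table per library, with 44968 gene entries and 5 summary entries each. The submitters' processing notes name Bowtie 1.2.2, HTSeq and edgeR. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. The summary entries stayed out of library sizes and tests. Their shares of all reads per library were 1.71% to 4.60% in no feature, 4.59% to 8.45% ambiguous and 16.3% to 39.8% not aligned; the other summary entries were 0. The authors also deposited tables of log2 fold changes, p-values and false discovery rates of daf-2 RNAi and of pitr-1 RNAi against empty vector for 12395 genes, made with edgeR and a batch correction on the libraries of the compared groups, per the notes in the same workbook. The variable used for that correction is not stated there. Those values were set beside the values computed here and entered no test.

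Gene names came from the authors' tables for 12395 identifiers and from the sequence names of the Ensembl release 115 annotation for 32167 more; 406 identifiers matched neither. Of the gene entries, 31072 had a count in at least 1 library. The counts include 22 ribosomal RNA genes and 14 mitochondrial genes.

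Calls rest on edgeR 4.0.16 in R 4.3.3: counts as deposited, TMM normalization, filterByExpr (14664 genes kept), the robust quasi-likelihood fit of all 12 libraries with 1 coefficient per group, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. Positive log2 fold changes mean higher in the first group named; CPM stands for counts scaled to the TMM-adjusted library size. This fit held no term for the replicate number. Errors of log2 fold changes are approximate standard errors (SE). They are the absolute log2 fold change divided by the square root of the F statistic of the edgeR test, and so restate that test. Errors of CPM are standard deviations (SD) over 4 libraries.

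Whether the replicate numbers pair the libraries was checked, before any calls were compared, by correlating deviations from the group means over genes. The correlation between same-numbered libraries was 0.137 to 0.505 for daf-2 RNAi and empty vector, 0.104 to 0.508 for pitr-1 RNAi and empty vector, and 0.434 to 0.610 for daf-2 and pitr-1 RNAi. Some libraries correlated more with a library of another number: daf-2 RNAi replicate 1 and empty vector replicate 3 at 0.492 against 0.210 and 0.137 with their own numbers. For pitr-1 RNAi replicate 1 and empty vector replicate 3 it was 0.381 against 0.212 and 0.104. pitr-1 RNAi replicate 2 correlated at 0.490 with a daf-2 RNAi library of another number, against 0.434 with that of its own. Every same-numbered pair passed the limit of 0.1 set beforehand, so values from a fit with the replicate number as a block are printed where they change a call or a count; the pairing comes from the data and not from the labels. The common biological coefficient of variation was 0.367 without the block (9 residual degrees of freedom) and 0.240 with it (6 residual degrees of freedom).

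The design of each test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 30 gene lists, each with at least 3 measured members. They cover cuticle collagens, molting and epidermal secreted proteins, vitellogenins, genes reported higher and genes reported lower when insulin-like signalling is low, insulin-like signalling components, insulin-like peptides, phosphate transporters and acid phosphatases, and the RNA interference pathway. They also cover germline and maternal transcripts, sperm proteins, early embryo zygotic genes, histones, DNA replication and cell cycle, ribosomal proteins, heat shock proteins, the unfolded protein response, xenobiotic detoxification, innate immune effectors and the intracellular pathogen response. The rest are fatty acid synthesis, beta-oxidation, autophagy and lysosomal lipases, gluconeogenesis and trehalose metabolism, mitochondrially encoded genes, and markers of neurons, FMRFamide-like neuropeptides, body wall muscle, pharynx and intestine. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with the preset correlation of 0.01, and Benjamini-Hochberg adjustment over the 30 lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. Fry tests whether the members of a list move one way on balance and does not compare the list with other genes.

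The rule for named genes takes the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 1 CPM and no overlap between the groups, 5 and 5 for the direct comparison, or the 3 genes of lowest p where none passed in a direction. It also takes daf-2, pitr-1 and hrde-1, and up to 4 members of lowest p from each list that was called. The same rule was applied to the fit with the block as an addition made after seeing the data.

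The alternatives planned were DESeq2 size factors, upper quartile and no normalization, no low count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, edgeR's exact test, only the 8 libraries of a comparison, the replicate block, an adjusted p of 0.1, a minimum change of 1.5-fold, and leaving out each library in turn. Added after seeing the data were removal of ribosomal RNA and mitochondrial genes, replicates 2 to 4 only, replicates 2 and 4 only, the block together with other settings, and the fit without the 3 libraries of highest pos-1. A list of heme-responsive genes was added then as well.

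Each fit was tested in 1 run on its own simulated counts. These had the gene means and library sizes of the 12 libraries, 14664 genes and known changes in daf-2 RNAi against empty vector. Counts for the fit without the block held no differences between replicate numbers. Counts for the fit with it held those differences and the spread left after them. The values below therefore do not compare the fits on the same data. Without the block the fit recovered 1.49% of the 1.5-fold, 16.4% of the 2-fold and 62.1% of the 4-fold changes; with it, 2.99%, 31.3% and 75.8%. Of the genes called, 1 of 54 without the block and 9 of 82 with it were unchanged in the simulation. In that run calls with the block held more false ones than the 5% aimed at. In simulated pitr-1 RNAi against empty vector, which held no change, each fit called 0 genes. Fold changes against the shared empty vector libraries were compared with 40 simulations of unchanged groups. Group differences in library measures were tested with exact two-sided permutation tests (70 permutations for 4 against 4 libraries, smallest p 0.0286).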

Results

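Gene expression was measured by mRNA sequencing in arrested L1 larvae whose parents had been fed bacteria carrying an empty vector or expressing double-stranded RNA against daf-2 or pitr-1. daf-2 encodes the insulin/IGF receptor of C. elegans, and hrde-1, which is mutated in all animals here, encodes a nuclear Argonaute needed for inherited gene silencing in the germline. Each group held 4 libraries. Counts assigned to genes ranged from 7737184 to 11490429 per empty vector library, from 9640590 to 10502750 per daf-2 RNAi library and from 5907286 to 10345381 per pitr-1 RNAi library.

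Ribosomal RNA took 36.03% ± 10.2 of the gene counts in empty vector libraries, 25.3% ± 7.90 in daf-2 RNAi and 26.3% ± 12.35 in pitr-1 RNAi libraries (SD, n = 4 each). These shares did not differ detectably from empty vector in tests that ignored the replicate numbers (exact permutation p = 0.143 and 0.286). There were 18 library tests in all, each with an adjusted p of at least 0.857. By replicate number, the share was higher than in empty vector in 1 of 4 pairs for daf-2 RNAi and 0 of 4 for pitr-1 RNAi. Without ribosomal RNA, 3416305 to 8681660 counts per library remained. Mitochondrial transcripts took 2.67% to 5.51% in the libraries of replicates 1 and 3 and 0.606% to 0.950% in those of replicates 2 and 4. On 9898 genes of at least 5 CPM, the first principal component held 51.8% of the variance, and 86.2% of it lay between the 4 replicate numbers against 0.631% between RNAi groups. Replicates 2 and 4 lay at 21.5 to 35.9 on it in every group, replicate 1 at −64.3 to −22.2, and replicate 3 at −38.6 in empty vector but at −1.37 in daf-2 RNAi and −4.85 in pitr-1 RNAi.

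**Figure D1:**
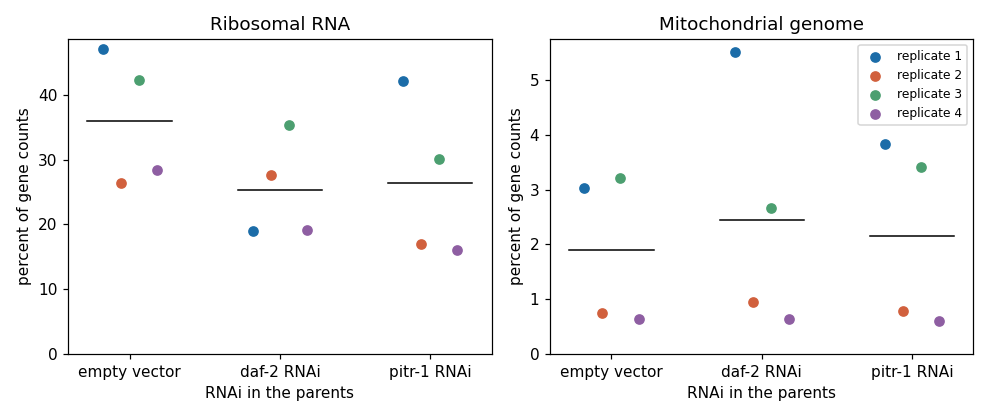
Ribosomal RNA and mitochondrial transcripts as a percent of gene counts in each of the 12 libraries, with points coloured by replicate number and a black line at each group mean. Mitochondrial shares lay at 2.67% or above in replicates 1 and 3 and at 0.950% or below in replicates 2 and 4 of every group.

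The targeted genes were measured in every library. daf-2 RNA in the progeny was 85.3, 67.2, 46.6 and 62.2 CPM in empty vector replicates 1 to 4, 21.9, 61.1, 43.5 and 63.5 CPM after daf-2 RNAi of the parents, and 40.6, 63.7, 33.95 and 59.6 CPM after pitr-1 RNAi. Its log2 fold change was −0.46 ± 0.31 (SE, n = 4) in daf-2 RNAi and −0.40 ± 0.32 in pitr-1 RNAi progeny, and neither passed the edgeR test. pitr-1, named as a relative of PiT-family phosphate transporters, stood at 217 ± 28.6 CPM in empty vector, 224 ± 52.4 in daf-2 RNAi and 212 ± 73.5 in pitr-1 RNAi progeny (SD, n = 4), with a log2 fold change of −0.04 ± 0.24 after pitr-1 RNAi. hrde-1 stood at 3.76 ± 0.947, 3.46 ± 1.37 and 3.37 ± 0.877 CPM in the 3 groups (SD, n = 4). The RNAi was applied to the parents, so RNA of the target in progeny neither checks nor contradicts the labels.

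The first comparison asks how gene expression in starved progeny differs after daf-2 RNAi of the parents. RNA of the parents was not measured, so effects of the RNAi in parents and in progeny cannot be separated. sod-3, the mitochondrial manganese superoxide dismutase and a well known target of the transcription factor DAF-16, rose from 10.2 ± 1.79 to 29.5 ± 6.76 CPM, a log2 fold change of 1.52 ± 0.21 (SE, n = 4). The neighbouring family members fipr-22 and fipr-23, which encode small secreted peptides, rose from 6.95 ± 1.31 to 29.2 ± 8.28 CPM and from 7.09 ± 1.15 to 25.6 ± 5.25 CPM, with log2 fold changes of 2.07 ± 0.26 and 1.84 ± 0.26. Reads shared between these similar genes leave the split between them uncertain. T28C6.10 rose from 1.54 ± 0.562 to 7.53 ± 2.02 CPM, and cpr-4, a cathepsin B-like cysteine protease, fell from 45.9 ± 14.7 to 8.99 ± 3.33 CPM (log2 fold changes 2.28 ± 0.34 and −2.35 ± 0.32).

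These 5 genes were the calls of the edgeR quasi-likelihood test, with Benjamini-Hochberg adjusted p of 0.0167 for sod-3, fipr-22, fipr-23 and cpr-4 and 0.0299 for T28C6.10. Values of the 2 groups did not overlap in any of them, which chance gives for 2.86% of genes with 4 against 4 libraries. T28C6.10 and fipr-23 were no longer called when any 1 of the 8 libraries was left out (edgeR adjusted p 0.0621 to 0.159 and 0.0585 to 0.127). sod-3 kept its call only without empty vector replicate 4 (edgeR adjusted p = 0.0343) and otherwise had an adjusted p of 0.0510 to 0.127. fipr-22 and cpr-4 lost theirs without empty vector replicate 2 or 3 (0.0631 and 0.0621 for both genes), daf-2 RNAi replicate 2 (0.0612 and 0.0867) or daf-2 RNAi replicate 4 (0.0510 each). cpr-4 also lost its call without daf-2 RNAi replicate 1 (0.0662). Over all omissions the log2 fold changes stayed at 2.08 to 2.54 for T28C6.10, 1.86 to 2.18 for fipr-22, 1.69 to 1.97 for fipr-23, 1.36 to 1.67 for sod-3 and −2.56 to −2.19 for cpr-4. Leaving out empty vector replicate 2, empty vector replicate 3, daf-2 RNAi replicate 2 or daf-2 RNAi replicate 4 ended all 5 calls. The count was 1 without daf-2 RNAi replicate 1, 2 without empty vector replicate 1 or daf-2 RNAi replicate 3, and 3 without empty vector replicate 4.

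With the replicate block, 27 genes rose and 19 fell, among them all 5 named above, and each of the 46 moved the same way in all 4 pairs. This fit calls genes by their differences within replicate numbers, so that agreement is no separate evidence for them. sod-5, a cytosolic superoxide dismutase, rose from 12.7 ± 4.73 to 68.3 ± 40.7 CPM (SD, n = 4; log2 fold change 2.33 ± 0.32 with the block; edgeR adjusted p = 0.00889). The largest increases were in alh-2, an aldehyde dehydrogenase, and D1086.9, with log2 fold changes of 3.14 ± 0.61 and 3.04 ± 0.31. djr-1.2, a relative of human DJ-1, rose by 2.86 ± 0.46 and the adenine nucleotide translocator ant-1.2 by 2.66 ± 0.48 on the log2 scale. fipr-26, F56D6.9 and F55B12.10 rose by 2.54 ± 0.35, 2.02 ± 0.21 and 1.99 ± 0.38 on the log2 scale. Of the genes that fell, acox-3 and acox-1 encode acyl-CoA oxidases of peroxisomal beta-oxidation (−1.42 ± 0.27 and −1.22 ± 0.23), cpr-1 a gut cysteine protease (−1.33 ± 0.21) and pept-1 the intestinal oligopeptide transporter (−0.75 ± 0.14). F10C1.9, F45E10.2, the C-type lectin clec-7 and the solute carrier slc-17.6 fell as well, with log2 fold changes of −1.40 ± 0.25, −1.15 ± 0.19, −1.13 ± 0.18 and −0.93 ± 0.18. Without the block the other 41 genes were not called. The count with it was 181 without replicate 1, 6 without replicate 2, 15 without replicate 3 and 8 without replicate 4.

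**Figure D2:**
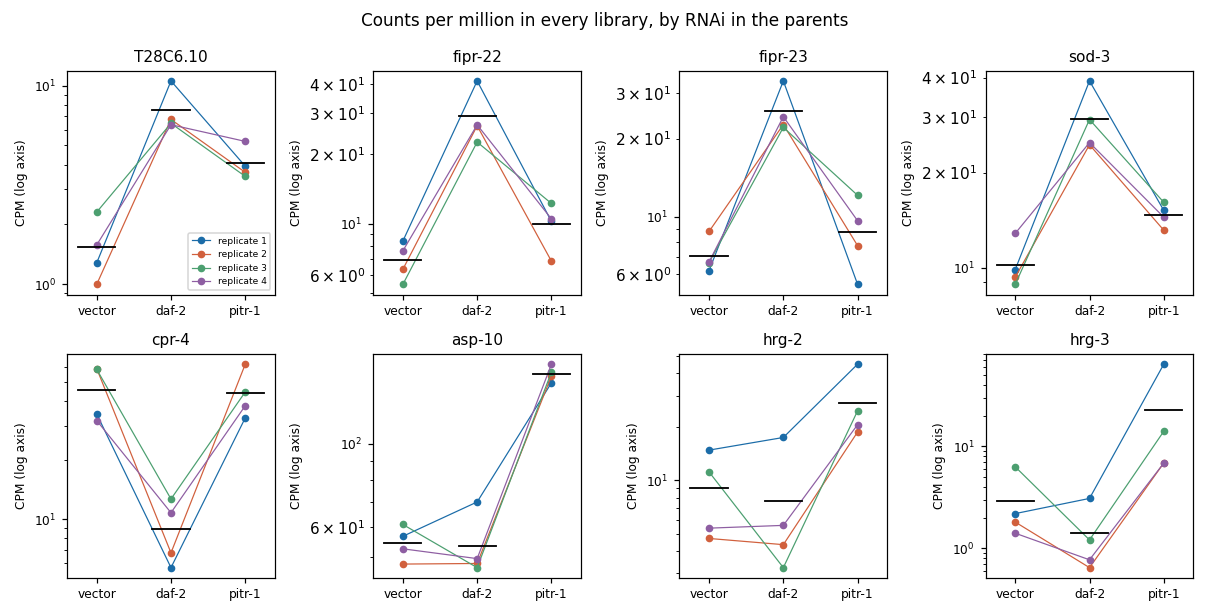
CPM on a log axis of 8 genes in each library, by RNAi in the parents; lines join libraries of the same replicate number and black bars are group means. sod-3 lay higher and cpr-4 lower in all 4 daf-2 RNAi libraries than in any empty vector library, and asp-10 lay at 145 CPM or above in all 4 pitr-1 RNAi libraries.

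Genes reported higher when insulin-like signalling is low rose as a group in daf-2 RNAi progeny: 18 of 22 measured members lay above 0, with a median log2 fold change of 0.24, and the list median was higher in 4 of 4 pairs. Camera called it (adjusted p = 7.0e-06). This call held with an estimated correlation (adjusted p = 0.0120) and in fry (adjusted p = 0.000544), but not with an estimated correlation and the block (adjusted p = 0.0558). Of its members 1, sod-3, passed over all genes, and 2 passed when adjusted over the list alone; with the block these counts were 4 higher and 10 higher with 2 lower. The late embryogenesis abundant-like gene lea-1 stood at 103.6 ± 29.7 against 37.1 ± 9.19 CPM (log2 fold change 1.48 ± 0.24 with the block; edgeR adjusted p = 0.123, and 0.0187 with the block), and cyp-35B1 at 11.5 ± 2.505 against 6.32 ± 2.03 CPM (SD, n = 4). The metallothionein mtl-1, named here after its values were seen, and the transthyretin-like ttr-44 rose by 0.94 ± 0.14 and 0.62 ± 0.12 on the log2 scale with the block.

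Intestine markers fell in daf-2 RNAi progeny, with 15 of 15 members below 0, a median log2 fold change of −0.20 and a mean of −0.47 (camera adjusted p = 4.11e-08; adjusted p = 0.230 with an estimated correlation). cpr-4 passed over all genes and 3 members passed when adjusted over the list alone; with the block these were 3, cpr-4, cpr-1 and pept-1, and 4. elt-2, the GATA factor of the intestine, stood at 8.03 ± 1.25 against 13.1 ± 2.32 CPM and did not pass. The calls of these 2 lists held in camera without any 1 of the 8 libraries. The median differences in mean log2 CPM over these omissions were 0.21 to 0.41 for genes reported higher when insulin-like signalling is low, against 0.27 with all libraries. For intestine markers they were −0.31 to −0.14, against −0.22, and nearest 0 without daf-2 RNAi replicate 1.

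DNA replication and cell cycle genes and germline and maternal transcripts were higher as groups in daf-2 RNAi progeny, with 28 of 30 and 29 of 31 members above 0 and median log2 fold changes of 0.74 and 0.68 (camera adjusted p = 5.79e-09 and 3.48e-05). With an estimated correlation neither was called (adjusted p = 0.501 and 0.681). No member passed over all genes or when adjusted over the list alone in the edgeR test; with the block 6 replication genes and 2 germline genes passed when adjusted over the list alone. pos-1, a maternal RNA-binding protein of the early embryo, averaged 38.1 ± 32.2 against 7.01 ± 4.36 CPM (SD, n = 4). The replication factor mcm-3 averaged 17.9 ± 9.31 against 7.29 ± 1.85 CPM and the sliding clamp pcn-1 31.4 ± 20.1 against 12.2 ± 3.68 CPM (SD, n = 4). pos-1 was highest in daf-2 RNAi replicate 2, daf-2 RNAi replicate 3 and pitr-1 RNAi replicate 3, at 68.2, 63.2 and 87.3 CPM, and 4.19 to 18.97 CPM in the other 9 libraries. These 3 libraries were picked after the data were seen, by a member of the germline list, so leaving them out tests neither list. The replication median was higher in 4 of 4 pairs (0.0134 to 1.44) and the germline median in 3 of 4. The germline list was not called without daf-2 RNAi replicate 2 (camera adjusted p = 0.0932), where its median difference in mean log2 CPM was 0.41 against 0.58 with all libraries.

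FMRFamide-like neuropeptides, ribosomal proteins, innate immune effectors and fatty acid synthesis genes were lower as groups in daf-2 RNAi progeny by the preset test. Of their members, 25 of 30, 65 of 79, 103 of 160 and 14 of 17 lay below 0, with median log2 fold changes of −0.24, −0.10, −0.17 and −0.17 (camera adjusted p = 0.000702, 0.00516, 0.0170 and 0.0238). None held with an estimated correlation (adjusted p = 0.752, 0.752, 0.659 and 0.266), and none was called without the 3 libraries of highest pos-1 (0.652, 0.318, 0.551 and 0.228). Among their members flp-3 stood at 251 ± 52.1 against 329.6 ± 56.6 CPM and rps-5 at 2335 ± 250 against 2766 ± 678 CPM (SD, n = 4). clec-7 stood at 8.79 ± 1.45 against 18.96 ± 2.28 CPM and the acetyl-CoA carboxylase pod-2 at 132 ± 33.02 against 180 ± 17.7 CPM (SD, n = 4). In the edgeR test none of these lists had a member past the threshold over all genes. 1 immune effector passed when adjusted over the list alone, and clec-7 fell with the block. Against the direction of the immune list, clec-87 averaged 58.0 ± 51.1 against 11.4 ± 6.66 CPM (SD, n = 4) and did not pass. Leaving out empty vector replicate 3 or daf-2 RNAi replicate 2 ended all 4 calls (camera adjusted p = 0.272 and 0.107, 0.581 and 0.274, 0.318 and 0.174, 0.241 and 0.0932 in the order above). Their median differences in mean log2 CPM were −0.24, −0.0939, −0.15 and −0.18 with all libraries and −0.0675, 0.0285, −0.0210 and −0.0937 without empty vector replicate 3. Without daf-2 RNAi replicate 2 they were −0.12, 0.00888, −0.13 and −0.18, so the ribosomal median changed sign in both cases. Without the 3 libraries of highest pos-1 they were −0.0499, −0.0191, −0.0907 and −0.16, so fatty acid synthesis lost its call there with little change in its median. Those 3 include daf-2 RNAi replicates 2 and 3, which leaves replicates 1 and 4 of that group. That loss therefore contains the omission of daf-2 RNAi replicate 2 and is no separate result. Leaving out daf-2 RNAi replicate 4 ended 3 of the 4 calls (0.0544 for neuropeptides, 0.105 for immune effectors and 0.130 for fatty acid synthesis; medians −0.13, −0.11 and −0.13). Leaving out empty vector replicate 1 ended that of fatty acid synthesis (0.0997; median −0.13).

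With the block, camera also called molting genes, insulin-like peptides, the RNA interference pathway and autophagy genes (adjusted p = 0.0478, 0.0328, 0.0180 and 0.0478). Without it their adjusted p was 0.0679 each, and with an estimated correlation and the block none was called (adjusted p = 0.551, 0.759, 0.456 and 0.421). Autophagy genes and lysosomal lipases, with 19 of 30 members below 0, were called by fry (adjusted p = 0.00924).

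The second comparison asks the same of pitr-1 RNAi in the parents. asp-10, an aspartyl protease also named hrg-7 for its response to heme, rose from 54.4 ± 5.63 to 154 ± 7.35 CPM, a 2.83-fold increase (log2 fold change 1.499 ± 0.18, n = 4). It was 145 to 163 CPM in pitr-1 RNAi progeny and 47.7 to 60.9 CPM in empty vector progeny, and higher in 4 of 4 pairs. edgeR called no gene lower, with or without the block. The lectin clec-52 stood at 13.5 ± 2.67 against 28.9 ± 5.08 CPM and the patched-related ptr-13 at 8.37 ± 1.61 against 18.3 ± 5.08 CPM (SD, n = 4). The saposin-like spp-17 stood at 2.12 ± 0.383 against 5.25 ± 1.37 CPM. Each of the 3 was lower in 4 of 4 pairs, and none passed.

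asp-10 was the only call of the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.00924, and 0.000620 with the replicate block). 83 genes lay lower at an unadjusted p under 0.05, and 0 lower were called in DESeq2 or the exact test, against 1 lower in DESeq2 with the block, 1 with replicates 2 and 4 only and 22 with the block without replicate 1. asp-10 was not called without empty vector replicate 1, 2 or 4 or pitr-1 RNAi replicate 3 or 4 (edgeR adjusted p = 0.0781, 0.0893, 0.0828, 0.0514 and 0.0525). Over all omissions the log2 fold change was 1.44 to 1.55.

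Ribosomal protein genes were lower as a group in pitr-1 RNAi progeny, with 61 of 79 members below 0 and a median log2 fold change of −0.15 (camera adjusted p = 2.80e-06; adjusted p = 0.631 with an estimated correlation). rpl-18 stood at 1014 ± 82.4 against 1228 ± 102 CPM and rps-4 at 1314 ± 151 against 1613 ± 87.5 CPM (SD, n = 4), and no member passed. This call held without the 3 libraries of highest pos-1 (camera adjusted p = 0.00410) and was lost without empty vector replicate 3 (0.0626). The median difference in mean log2 CPM was −0.16 with all libraries, −0.15 without those 3 and −0.0259 without empty vector replicate 3.

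DNA replication genes, germline transcripts and molting and epidermal genes were higher as groups, with 27 of 30, 28 of 31 and 32 of 40 members above 0 and median log2 fold changes of 0.48, 0.58 and 0.43 (camera adjusted p = 6.15e-05, 0.000157 and 0.00588). With an estimated correlation none was called (adjusted p = 0.631, 0.631 and 0.568). The molting list was not called without the 3 libraries of highest pos-1 either (camera adjusted p = 0.211, median 0.15), which is no test of the other 2 lists. Of those 3 only pitr-1 RNAi replicate 3 belongs to this comparison, so this loss repeats the omission of that library given below. The replication median was higher in 2 of 4 pairs and the germline median in 3 of 4. Leaving out pitr-1 RNAi replicate 3 ended all 3 calls (0.435, 0.193 and 0.220), leaving out empty vector replicate 3 those of the germline and molting lists (0.0626 each), and leaving out pitr-1 RNAi replicate 2 that of the molting list (0.0535). Their median differences in mean log2 CPM were 0.39, 0.50 and 0.29 with all libraries and 0.19, 0.35 and 0.15 without pitr-1 RNAi replicate 3. Without empty vector replicate 3 those of the germline and molting lists were 0.34 and 0.28, and without pitr-1 RNAi replicate 2 that of the molting list was 0.28. In pitr-1 RNAi replicate 3 pcn-1 stood at 57.0 CPM against 13.1 to 14.4 CPM in the other 3 of its group, and cyb-1 at 43.2 against 8.90 to 13.4 CPM.

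Pharynx markers were higher and intestine markers lower by the preset test, with 17 of 21 members above and 13 of 15 below 0 and medians of 0.22 and −0.17 (camera adjusted p = 0.0375 each). With an estimated correlation neither was called (adjusted p = 0.631 each), and without the 3 libraries of highest pos-1 the values were 0.120 and 0.419. The median differences in mean log2 CPM were 0.30 and −0.18 with all libraries and 0.34 and −0.10 without those 3, so the pharynx median did not shrink. Of those 3 only pitr-1 RNAi replicate 3 belongs to this comparison, so its omission below gives the same medians. The largest pharynx values came from pitr-1 RNAi replicate 3, where abu-14 stood at 178 CPM and phat-4 at 56.6 CPM. The aspartyl proteases asp-1 and asp-5, expressed in the intestine, stood at 1924 ± 223 against 2409 ± 178 CPM and 941 ± 48.3 against 1106 ± 84.6 CPM (SD, n = 4). Both calls were lost without empty vector replicate 3 or pitr-1 RNAi replicate 3 (camera adjusted p = 0.378 and 0.193 for pharynx, 0.0626 and 0.407 for intestine), with pharynx medians of 0.19 and 0.34 and intestine medians of −0.18 and −0.10. The pharynx call was also lost without empty vector replicate 1 or 4 or pitr-1 RNAi replicate 2 (0.0848, 0.0520 and 0.153; medians 0.19, 0.42 and 0.18). The intestine call was also lost without empty vector replicate 2 or pitr-1 RNAi replicate 4 (0.222 and 0.0718; medians −0.16 and −0.20).

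Genes reported higher when insulin-like signalling is low had a median log2 fold change of 0.27 in pitr-1 RNAi progeny. Of the members 16 of 22 lay above 0, and the list median was higher in 4 of 4 pairs. Camera called this list with the block (adjusted p = 0.0234) but not without it (0.0548). With an estimated correlation and the block it was not called either (adjusted p = 0.495). Insulin-like peptides were called lower with the block as well (camera adjusted p = 0.0472; adjusted p = 0.720 with an estimated correlation), and without it 17 of 24 lay below 0 (0.115). No member of any of the 30 lists passed in the edgeR test without the block, over all genes or when adjusted over the list alone.

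The third comparison sets daf-2 RNAi directly against pitr-1 RNAi. The empty vector libraries still enter its filter, scaling and estimate of spread. cpr-4 was lower in daf-2 RNAi progeny, at 8.99 ± 3.33 against 44.4 ± 12.64 CPM, and asp-10 lower, at 53.5 ± 11.01 against 154 ± 7.35 CPM (SD, n = 4). Their log2 fold changes were −2.31 ± 0.32 and −1.52 ± 0.18 (SE). ugt-1, a glucuronosyltransferase, stood at 18.5 ± 6.25 against 5.04 ± 0.404 CPM, and with fipr-22 (log2 fold change 1.56 ± 0.25) and fipr-23 (1.53 ± 0.25) came closest to a call among genes higher in daf-2 RNAi progeny.

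The edgeR quasi-likelihood test called cpr-4 and asp-10 (Benjamini-Hochberg adjusted p = 0.0271 and 0.00755). At an unadjusted p under 0.05, 164 genes lay higher, of which edgeR called 0, where DESeq2 called 11 and the exact test 5. Fitted on only the 8 libraries of this comparison, edgeR called 0 genes, with 323 at an unadjusted p under 0.05. On the same 8 libraries the exact test (10 genes) and edgeR with the block (60 genes) called both cpr-4 and asp-10, as did DESeq2 on all 12 (22 genes). ugt-1, fipr-22 and fipr-23 had an edgeR adjusted p of 0.0793 each, and 0.00764, 0.00764 and 0.0241 with the block. asp-10 was not called without daf-2 RNAi replicate 2 or 4 (edgeR adjusted p = 0.0898 and 0.0730). cpr-4 was not called without daf-2 RNAi replicate 1, 2 or 4 (0.106, 0.166 and 0.0920) or pitr-1 RNAi replicate 2, 3 or 4 (0.0982, 0.107 and 0.0662). Over all omissions the log2 fold changes were −1.68 to −1.46 for asp-10 and −2.5154 to −2.1002 for cpr-4.

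With the block, 12 genes were higher and 10 lower in daf-2 than in pitr-1 RNAi progeny, cpr-4 and asp-10 among them. The heme-responsive genes hrg-3, which encodes a secreted heme chaperone, and hrg-2, which encodes a membrane heme-binding protein, were lower with log2 fold changes of −3.70 ± 0.48 and −1.99 ± 0.27, and R193.2 with −1.66 ± 0.28 (edgeR adjusted p = 0.00651, 0.00764 and 0.0259). F56D6.9, D1086.9, spp-17, ugt-1 and the isoprenylcysteine methyltransferase icmt-1 were higher, with log2 fold changes of 2.18 ± 0.21, 2.04 ± 0.29, 1.83 ± 0.27, 1.80 ± 0.25 and 1.66 ± 0.26. The count of calls with the block was 80 without replicate 1, 3 without replicate 2, 15 without replicate 3 and 5 without replicate 4.

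Genes reported higher when insulin-like signalling is low were higher in daf-2 than in pitr-1 RNAi progeny, with 16 of 22 members above 0 and a median log2 fold change of 0.24 (camera adjusted p = 0.00483; adjusted p = 0.0996 with an estimated correlation; fry adjusted p = 0.0343). 2 members passed when adjusted over the list alone and 0 over all genes in the edgeR test. With the block sodh-1, an alcohol dehydrogenase, was lower (log2 fold change −1.35 ± 0.22, adjusted p = 0.0264), against the direction of the list. Intestine markers were lower, with 10 of 15 members below 0 and a median of −0.11, 1 called and 3 when adjusted over the list alone (camera adjusted p = 0.00160; adjusted p = 0.840 with an estimated correlation). The intestine call was lost without daf-2 RNAi replicate 1 (0.0851), where the median difference in mean log2 CPM was −0.0415 against −0.11.

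FMRFamide-like neuropeptides and innate immune effectors were lower in the direct comparison by the preset test, with 29 of 30 and 114 of 160 members below 0 and medians of −0.22 and −0.17 (camera adjusted p = 0.0235 and 0.0393; adjusted p = 0.840 each with an estimated correlation). flp-6 stood at 105 ± 9.18 against 121 ± 10.4 CPM, and clec-7 at 8.79 ± 1.45 against 20.4 ± 3.19 CPM with a log2 fold change of −1.21 ± 0.18 with the block (edgeR adjusted p = 0.0112). Against the direction of the list, spp-17 was higher by 1.83 ± 0.27 with the block (edgeR adjusted p = 0.0112) and clec-52 by 0.95 ± 0.19 (0.0782). Both calls were lost without daf-2 RNAi replicate 2, daf-2 RNAi replicate 3, daf-2 RNAi replicate 4 or pitr-1 RNAi replicate 1 (camera adjusted p = 0.477, 0.0740, 0.254 and 0.276 for neuropeptides, and 0.340, 0.0611, 0.172 and 0.809 for immune effectors). In that order the median differences in mean log2 CPM were −0.0812, −0.16, −0.0970 and 0.13 for neuropeptides, against −0.19 with all libraries, and −0.0723, −0.11, −0.0400 and −0.0674 for immune effectors, against −0.11. Without the 3 libraries of highest pos-1 the camera adjusted p was 0.749 and 0.450, with medians of −0.0355 and −0.0545. Those 3 include daf-2 RNAi replicates 2 and 3, each of which ended both calls when left out alone. With the block camera also called DNA replication genes higher (0.0295, from 0.0547; adjusted p = 0.873 with an estimated correlation) and pharynx markers lower (0.0368, from 0.0891; adjusted p = 0.712).

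**Figure D3:**
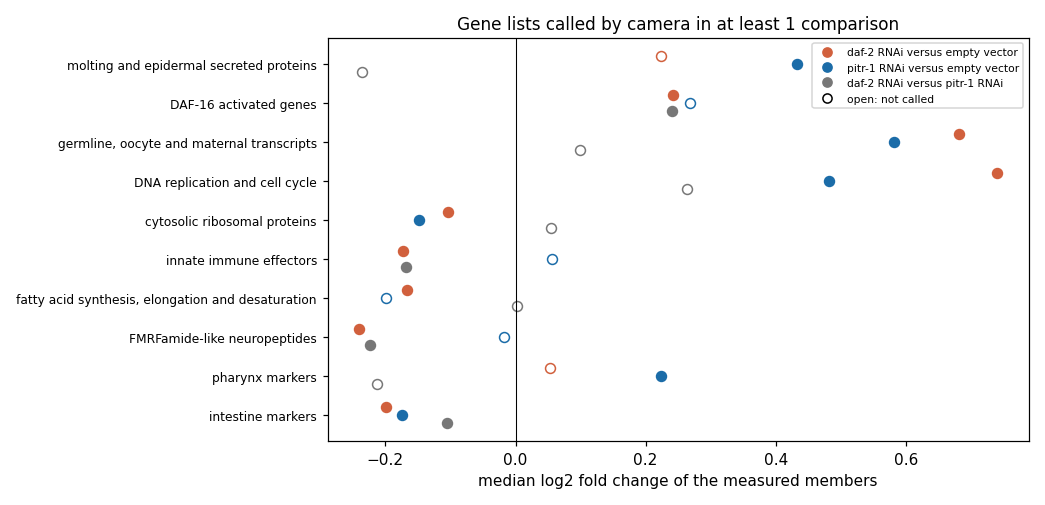
Median log2 fold change of the members of 10 gene lists in the 3 comparisons; filled points mark lists called by camera with the preset correlation and open points lists not called. The list of genes reported higher when insulin-like signalling is low had medians of 0.24 in daf-2 RNAi and 0.27 in pitr-1 RNAi against empty vector. It was not called in the latter. Its median was 0.24 in daf-2 against pitr-1 RNAi.

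All directions above are relative to the other genes of the same libraries after TMM scaling. Scaled by the total count alone, the median over all genes moved to 0.25 in daf-2 RNAi, 0.27 in pitr-1 RNAi and −0.03 in the direct comparison. Against empty vector this exceeded the size of the ribosomal, immune, neuropeptide, intestine and fatty acid synthesis medians. The total count includes ribosomal RNA, which averaged 36.03% in empty vector, 25.3% in daf-2 RNAi and 26.3% in pitr-1 RNAi libraries. A larger share in empty vector lowers the other genes there on that scale, which is the direction of both shifts. The total count is therefore not a neutral scale for these medians. How much of the shifts under total-count scaling came from ribosomal RNA was not tested. No gene was called by edgeR with that scaling in any of the 3 comparisons, with 529, 297 and 203 genes at an unadjusted p under 0.05; DESeq2 with its own size factors called 50, 1 and 22.

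The log2 fold changes of the 2 RNAi treatments against empty vector were correlated across 14664 genes, which are not independent replicates (r = 0.609, same sign in 71.3% of genes). Unchanged groups set against the same empty vector libraries gave r = 0.505 ± 0.00957 (SD, 40 simulations; highest 0.523) and the same sign in 66.8%. The covariance was 0.102 against a simulated 0.0606, a difference of 0.0416. With 2 separate empty vector libraries for each treatment the correlation averaged 0.00433 over 6 splits (−0.195 to 0.111) and the covariance −0.00205. These sets of 2 also differ in replicate numbers, so the values do not show what separate controls alone would give. At an unadjusted p under 0.05 with the block, 123 genes were higher in both, of 619 in daf-2 and 298 in pitr-1 RNAi, where independent lists share 12.58 and unchanged groups with shared controls 84.2 (highest 103). Lower in both were 74 genes, of 588 and 237, where independent lists share 9.503 and unchanged groups 55.4 (highest 74). The simulated genes vary independently of each other, and the simulated groups hold no deviations shared by same-numbered libraries of the 2 RNAi groups alone. Deviations from group means correlated at 0.434 to 0.610 between those libraries, against 0.104 to 0.508 with empty vector. Such sharing raises r without any effect of treatment, so the excess over the simulations is not assigned to the treatments.

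In the authors' deposited table, 20 genes were higher and 4 lower in daf-2 RNAi progeny at a false discovery rate under 0.05. They include all 5 genes called here without the block, and 19 of the 24 were also called with the block. Fitted with the block on only the 8 libraries of this comparison, edgeR called 24 genes, and these were the same 24 genes. In the deposited table for pitr-1 RNAi no gene lay under that limit (lowest value 0.0508, for asp-10, with a log2 fold change of 1.51). Here edgeR called asp-10 from all 12 libraries without and with the block (adjusted p = 0.00924 and 0.000620). It also called asp-10 with the block on only the 8 libraries of that comparison. The source of this difference from the deposited table was not tested. The authors' log2 fold changes correlated with those of the fit with the block at r = 0.995 for daf-2 and 0.991 for pitr-1 RNAi, and with those of the fit without it at 0.978 and 0.934.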

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

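The tests of the first component against the maternal RNAi group, of germline transcripts and of heme-responsive genes were chosen only after the result was seen.

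In groups of 4 libraries, single libraries stood apart from the other 3 of their group in 34 of 267 groups tested, by the 95% limit of Dixon's test. Chance flags about 1 in 20 groups, and the genes tested are those named in the text, which do not vary independently. Of the genes, 10 stood apart in pitr-1 RNAi replicate 3, 7 in daf-2 RNAi replicate 1 and 6 in pitr-1 RNAi replicate 1.

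Among library measures, daf-2 RNAi replicate 3 stood apart with 10502750 gene counts against 9640590 to 9701471. The share of reads not aligned stood apart at 28.01% in empty vector replicate 1 (17.3% to 17.97% in the others) and at 39.8% in pitr-1 RNAi replicate 1 (17.3% to 20.2%).

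pitr-1 RNAi replicate 3 stood above the other 3 libraries of its group in oocyte, cell cycle and pharynx genes. There puf-5 was at 8.82 CPM, pcn-1 at 57.0, mcm-5 at 22.7 and cyb-1 at 43.2 CPM. The pharynx genes phat-1, phat-2, phat-4 and abu-14 were at 12.1, 37.8, 56.6 and 178 CPM against at most 1.22, 4.26, 13.2 and 29.4 CPM in the others. clec-87 was at 112 CPM (13.3 to 21.1 in the others) and djr-1.2 at 9.95 CPM (1.04 to 1.83).

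daf-2 RNAi replicate 1 stood above its group for T28C6.10 at 10.6 CPM, fipr-26 at 86.0, F55B12.10 at 28.7, asp-10 at 69.9, hrg-2 at 17.4 and flp-3 at 329 CPM, and below it for elt-2 at 6.17 CPM. pitr-1 RNAi replicate 1 stood above its group for pitr-1 at 322 CPM, hrg-3 at 63.9, flp-3 at 384, flp-28 at 278, flp-33 at 305.2 and wrt-9 at 5.50 CPM. Without that library the log2 fold change of pitr-1 against empty vector was the lowest over all omissions, −0.30.

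Other single libraries stood apart in 1 or a few genes. Empty vector replicate 3 was above its group for F55B12.10 at 6.06 CPM and hrg-3 at 6.31 CPM, empty vector replicate 1 for spp-17 at 7.30 CPM, and empty vector replicate 2 for pos-1 at 13.5 CPM. daf-2 RNAi replicate 3 was above its group for rps-9 at 3395 CPM, replicate 2 of that group below it for cyp-35B1 at 7.77 CPM, and replicate 4 below it for slc-17.6 at 6.95 CPM. pitr-1 RNAi replicate 4 was above its group for clec-52 at 17.5 CPM.

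Splitting the 8 libraries of a comparison into replicates 1 and 3 against 2 and 4, which parts no pair of equal numbers, gave 530 calls for daf-2 RNAi and empty vector, 1835 for pitr-1 RNAi and empty vector and 1756 for both RNAi groups, the highest of the other splits, against 5, 1 and 2 for the real groups, so in each, 2 of 35 splits gave as many calls, chance cannot be excluded, and the high counts point to a structure of the samples. The 8 splits that part all 4 pairs are too few for a share under 0.05. Among them the highest other without the block was 0 in all 3 comparisons. With the block, 1 of 8, the real split itself, gave as many calls as the real split in daf-2 RNAi against empty vector (real 46, highest other 1) and 1 of 8 in the direct comparison (real 22, highest other 0), but 2 of 8 in pitr-1 RNAi against empty vector (real 1, highest other 1). Of the first component, with scaling computed on its 9898 genes alone, only 0.636% lay between the maternal RNAi groups. Thinning the libraries to equal counts left the component at 49.2% of the variance, which argues against library depth as its whole source. Removing ribosomal RNA and mitochondrial genes left it at 51.4%, which decides nothing, since these 14 genes held 1.19% of the variance. The labels record no day or batch, so a shared day of culture, the exact age at freezing or a batch of libraries stays open and untested.

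Germline and replication transcripts were higher as lists in both RNAi groups, the replication median in 4 of 4 daf-2 RNAi and 2 of 4 pitr-1 RNAi pairs, and neither list was called with an estimated correlation (camera adjusted p = 0.681 and 0.501 in daf-2 RNAi, 0.631 each in pitr-1 RNAi). RNA of unhatched embryos might raise them, and germline and early embryo list medians correlated over the 12 libraries with replicate number means removed at r = 0.561 (permutation p = 0.0552; rho = 0.434, p = 0.163; adjusted p = 0.0884 over 8 relations), but without the 2 farthest libraries r was 0.122, so the relation rests on those. RNA of carried-over adults might do so too, and there the correlation with vitellogenins was −0.306 (permutation p = 0.334; rho = −0.196). Maternal RNAi itself might raise them, and the germline median was higher in 6 of 8 pairs, 3 of 4 in each RNAi group, and lower in both replicate-1 pairs. The 8 pairs share 4 empty vector libraries, so the 2 RNAi groups are not independent of each other here. These 3 explanations cannot be told apart, since the pairs are few and the early embryo and vitellogenin lists hold 13 and 4 measured members.

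Heme-responsive genes besides asp-10 stood higher in pitr-1 RNAi progeny, and neither the edgeR fit without the block nor that with it called them against empty vector. The rise was not seen in the replicate-1 pair alone. In pairs 2, 3 and 4, 6 of 8 measured members, asp-10 included, were higher in pitr-1 RNAi, or 5 of 7 besides asp-10 and 3 of the 5 below. Members were first seen among the top genes, which favours agreement between pairs. These counts are therefore no test of the replicate-1 libraries as the source. A response of the hrg genes beyond those called may be a candidate explanation: the 5 members that neither edgeR fit called in any comparison gave p = 0.0293 in camera with an estimated correlation and the block, 1 of 12 tests of these genes. The list was chosen because its members were seen among the top genes, so this is a hypothesis. Each RNAi clone is also a different bacterial food, so the target gene and the food cannot be separated here.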

How the results depend on the processing

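The tests without ribosomal RNA and mitochondrial genes, with replicates 2 to 4 or 2 and 4 only, with the block combined with another setting, and without the 3 libraries of highest pos-1 were chosen only after the result was seen; the others were planned. Counts of calls stayed within 1.5 times those reported with DESeq2 size factors, upper quartile normalization, a filter of 1 CPM in 4 libraries, a minimum of 1.5-fold and without ribosomal RNA and mitochondrial genes. Where a count or call changed below, the cause was not tested, except that fits on fewer libraries have fewer degrees of freedom.

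For daf-2 RNAi against empty vector, 5 genes were called in edgeR. The count was 0 with no normalization (529 at an unadjusted p under 0.05), 13 with no low count filter, 50 in DESeq2 (35 higher, 15 lower), 39 in edgeR's exact test, 1 with replicates 2 to 4, 15 with replicates 2 and 4, and 0 without the 3 libraries of highest pos-1 (280 unadjusted). With the replicate block it was 46, with the block on only the 8 libraries 24, with the block in DESeq2 176, and with the block without the 3 libraries 5. Leaving out each library in turn gave 0 to 3 calls, and with the block, leaving out each replicate number, 6 to 181.

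For pitr-1 RNAi against empty vector, 1 gene was called. The count was 0 with no normalization (297 unadjusted), 4 with replicates 2 and 4, 0 without the 3 libraries of highest pos-1 (166 unadjusted; DESeq2 on all libraries 1), and 8 with the replicate block in DESeq2. Leaving out each library gave 0 to 1 calls, and with the block, each replicate number, 0 to 31.

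For daf-2 against pitr-1 RNAi, 2 genes were called. The count was 0 with no normalization (203 unadjusted), 6 with no low count filter, 22 in DESeq2, 10 in the exact test, 0 on only the 8 libraries (323 unadjusted), 1 with replicates 2 to 4, 25 with replicates 2 and 4, 0 without the 3 libraries of highest pos-1 (204 unadjusted), and 7 at an adjusted p of 0.1. With the replicate block it was 22, with the block on only the 8 libraries 60, with the block in DESeq2 86, and with the block without the 3 libraries 5. Leaving out each library gave 0 to 2 calls, and with the block, each replicate number, 3 to 80. The block kept every gene call made without it and added 41 in daf-2 RNAi against empty vector and 20 in the direct comparison, part of them named.

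Of the 18 list calls, 1 held and 17 were lost with an estimated correlation, 2 held and 16 were lost in fry, all 18 held with the block, 14 held and 4 were lost with replicates 2 to 4, and 5 held and 13 were lost without the 3 libraries of highest pos-1, which were picked by a germline gene and so test neither the germline nor the replication lists. With each library left out, 106 tests kept the call, 35 lost it and 3 reversed the median. These were FMRFamide-like neuropeptides in the direct comparison, −0.40 to 0.13 over the omissions, and ribosomal proteins in daf-2 RNAi, 0.0285 without empty vector replicate 3 and 0.00888 without daf-2 RNAi replicate 2.

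Log2 fold changes of named genes kept direction and side of the threshold for all 111 with DESeq2 size factors and without ribosomal RNA and mitochondrial genes. With the block 81 did and 30 passed the threshold newly, a count that tests nothing, since genes named from that fit are among them. With replicates 2 to 4, 102 did, 1 passed newly, 6 lost the call and 2 reversed, pitr-1 in daf-2 RNAi to −0.0729 and daf-2 in the direct comparison to 0.10. Over omissions of a library 825 values kept both, 45 lost the call and 18 reversed, all in genes that were not called. Against empty vector the ranges were −0.13 to 0.12 for pitr-1 and −0.35 to 0.0903 for hrde-1 in daf-2 RNAi, and −0.30 to 0.0511 for pitr-1 and −0.31 (without pitr-1 RNAi replicate 3) to 3.25 for phat-2 in pitr-1 RNAi. In the direct comparison they were −0.23 to 0.18 for daf-2, −0.0845 to 0.35 for pitr-1, −0.17 to 0.26 for hrde-1, −0.81 to 0.10 for flp-28 and −0.96 to 0.40 for flp-33, both highest without pitr-1 RNAi replicate 1. The correlation of fold changes between the RNAi groups was 0.609, 0.630 with the replicate block and 0.00433 with 2 separate empty vector libraries for each. Those sets of 2 differ in replicate numbers, so the last value does not show what separate controls alone would give. At the depth, spread and group size of these libraries the simulated 1.5-fold changes were seldom called. Each on its own simulated counts, the fit without the block recovered 1.49% and the fit with it 2.99% in daf-2 RNAi against empty vector.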

Other observations

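The tests of heme-responsive genes and the correlations between list medians were chosen only after the result was seen; the tests of the 30 lists were planned.

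Genes of heme transport stood higher in pitr-1 RNAi than in empty vector progeny besides asp-10. With the block the log2 fold changes were 2.42 ± 0.45 for hrg-3, 1.64 ± 0.27 for hrg-2, 1.56 ± 0.55 for hrg-6, 1.25 ± 0.65 for hrg-4 and 1.00 ± 0.22 for the heme transporter hrg-1 (SE, n = 4), each higher in 4 of 4 pairs and none past the edgeR threshold against empty vector. hrg-9 and hrg-10 had log2 fold changes of −0.01 and −0.04. The 5 members that neither edgeR fit called gave p = 0.0293 in camera with an estimated correlation and the block, p = 0.0562 in daf-2 against pitr-1 RNAi and p = 0.478 in daf-2 RNAi against empty vector. These p-values are unadjusted, from 12 tests of these genes.

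Cytosolic heat shock proteins had high list medians in both RNAi groups without being called by camera: 11 of 14 members lay above 0 in daf-2 RNAi (median log2 fold change 0.97, adjusted p = 0.276) and 12 of 14 in pitr-1 RNAi (0.58, adjusted p = 0.336). Pairs went both ways, higher in 2 of 4 in each RNAi group, and with the block the medians were 0.54 and 0.33. Xenobiotic detoxification genes were not called as a group (88 of 159 above 0, median 0.06, camera adjusted p = 0.287), while 3 members passed when adjusted over the list alone in daf-2 RNAi; with the block ugt-1, gst-15 and cyp-34A9, named after their values were seen, rose by 1.54 ± 0.25, 0.88 ± 0.16 and 0.91 ± 0.17 on the log2 scale. Beta-oxidation genes were not called (camera adjusted p = 0.960), with 20 of 35 above 0, while 2 members passed as lower when adjusted over the list alone, and acox-1 and acox-3 fell with the block. Among molting genes, not called in daf-2 RNAi without the block, 2 members passed when adjusted over the list alone, and the hedgehog-like grd-3 and grd-10 rose with the block by 1.59 ± 0.16 and 1.25 ± 0.20. Autophagy genes and lysosomal lipases had 1 member lower when adjusted over the list alone, where the lipase lipl-1 had a log2 fold change of −1.98 ± 0.39 with the block (edgeR adjusted p = 0.0528).

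The other lists were not called by camera in any comparison. In daf-2 and pitr-1 RNAi against empty vector the median log2 fold changes were 0.24 and 0.20 for cuticle collagens, 0.08 and 0.24 for vitellogenins, 0.16 and 0.03 for genes reported lower when insulin-like signalling is low, and 0.03 and 0.02 for insulin-like signalling components. They were −0.07 and −0.06 for phosphate transporters and acid phosphatases, 0.27 and 0.25 for early embryo zygotic genes, 0.10 and 0.06 for sperm proteins, and −0.02 and 0.11 for histones. The unfolded protein response gave 0.05 and 0.08, the intracellular pathogen response 0.07 and −0.01, gluconeogenesis and trehalose metabolism 0.04 and −0.03, and mitochondrially encoded genes −0.05 and 0.07. Neuron markers gave −0.06 and −0.01 and body wall muscle markers 0.01 and 0.00. In daf-2 RNAi the median, the mean and the direction of camera differed in sign for vitellogenins, sperm proteins, histones, the unfolded protein response, beta-oxidation, gluconeogenesis and body wall muscle, none of them called. In the other comparisons they differed as well in lists of small medians, none of them called, such as immune effectors in pitr-1 RNAi (median 0.06, camera direction lower).

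Across the 12 libraries, germline list medians moved with those of DNA replication genes (r = 0.919, permutation p = 2e-05; rho = 0.909, p = 0.00015). With replicate number means removed r was 0.902 (permutation p = 0.00017; rho = 0.650, p = 0.0252), and 0.737 without the 2 farthest libraries. With heat shock proteins r was 0.408 (permutation p = 0.191) pooled and 0.570 (p = 0.0550; rho = 0.322) with the means removed, and 0.0247 without the 2 farthest. With early embryo genes the pooled r was 0.676 (permutation p = 0.0149; rho = 0.678, p = 0.0190; adjusted p = 0.0397 over 8 relations) and 0.503 without the 2 farthest. With vitellogenins it was −0.273 (permutation p = 0.388). For all these relations, here and among the flagged results, the permutations exchanged all 12 libraries freely. Libraries of the same replicate number are alike, and removing the number means ties their values, so these p-values may be too small.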
